A study of Danio rerio with 4 samples.

How the data were processed

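Single-cell RNA libraries were made from dissociated wild-type zebrafish embryos at 12 hours post fertilization, 1 library per group, each from 40 pooled embryos that were treated with dispase at 37 °C for 5 min. The values the authors deposited were raw counts of unique molecular identifiers (UMIs) per gene and cell barcode, with barcodes already called as cells. The matrix headers give a software version of 3.0.2 without a name. The processing notes list Seurat, R 3.5.2 and a mouse genome build, mm10, although every gene identifier is a zebrafish Ensembl identifier, so the zebrafish build is not known and no coordinates are given. Gene identifiers that shared a symbol were summed: 25107 identifiers gave 24429 symbols, 496 of them with several identifiers.

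Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12, igraph 0.11.9 and matplotlib 3.10.9. The filters, marker genes, gene lists, comparisons, the rule for naming genes and the first set of other settings were fixed before the data were examined. A cell was kept with at least 500 detected genes, at most 10% of UMIs from mitochondrially encoded genes and at most 4 times its library's median UMI count. In control, BMDBM, MPs and BMDBM+MPs this left out 281, 155, 246 and 273 barcodes for few genes, 50, 30, 30 and 34 for mitochondrial share, and 533, 149, 423 and 486 for many UMIs. Scrublet scores, computed per library, were then used to leave out the highest-scoring 0.8% per 1000 barcodes, which removed 650, 841, 1187 and 1775 putative doublets. Scrublet's automatic threshold had called 1, 0, 0 and 1534 barcodes and was not used. The fixed share removes more cells from a larger library.

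Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen over libraries, and 30 principal components, 15 neighbours and Leiden resolution 1 gave 39 clusters, without integration of the libraries. Clusters were named from 23 fixed marker lists, of whose genes 11 were absent from the table. A cluster took the name of its best class when the mean log2 fold of that class's markers over all other cells was at least 1 and at least 3 markers were 2-fold higher and seen in 10% of its cells. Its 10 top genes also had to hold no more markers of other classes than of its own. Clusters whose first and second class were both neural, with a mean of at least 0.5, were called neural of unresolved region. These naming thresholds were set after seeing the data. They left 7 clusters unnamed, with 24.2% of control cells, 15.5% with BMDBM, 14.8% with MPs and 17.6% with both, and a further 4.83%, 5.17%, 3.62% and 3.86% neural of unresolved region. Class names mean cells like the class, by markers alone.

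Each exposed library was compared with control, and the co-exposed library with each single exposure. With 1 library per group no test was run. Shares of cells carry exact Clopper-Pearson 95% intervals, and ratios of summed UMIs, scaled by each library's total (CPM), carry exact conditional binomial 95% intervals; both cover counting error only, as do normal intervals on differences of shares and on the departure from the product of single exposures. For rankings and list medians a count of 0 was replaced by a small positive count.

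Genes were named by rule. For each comparison over whole embryos, the 10 highest and 10 lowest ratios were named among genes with a symbol that is not clone-based, at least 20 CPM and 200 UMIs in the higher library, and an interval that stayed beyond a 25% difference. The rule named 5 each way in the pooled neural cells, 2 each way with at least 100 UMIs in every other class with 300 cells per library, 5 each way for the departure among genes at 20 CPM in every library, and 2 each way in each gene list. cyp19a1b, cyp1a, esr1, ahr2, elavl3, neurog1 and sox2 were to be given whatever their values; cyp19a1b was absent from the table, and 1 further gene is not reported here. eno1a, hspb1 and the chaperone genes hspa8, hsp90ab1 and hspa5 in the plot of chaperone genes belong to the fixed lists, and the sum of 6 inducible heat shock genes was chosen after their values were seen. Genes at least 2-fold apart were counted as a description of distance between libraries.

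The 21 fixed gene lists covered neural progenitor and regional identity, neurogenesis, neural crest, axon guidance and adhesion, aryl hydrocarbon receptor and xenobiotic metabolism, steroid and thyroid signalling, antioxidant and metal response, heat shock and unfolded protein response, DNA damage response and apoptosis, immediate early genes, immune response, S phase, G2 and M phase, endocytosis and lysosome, lipid and yolk handling, glycolysis, mitochondrially encoded genes, cardiac and vascular genes, an earlier stage (gastrula), a later stage (somitogenesis onward) and ribosomal proteins. Of their genes 17 were absent from the table. The median log2 ratio of members with at least 100 UMIs over the 4 libraries was set beside 10000 random lists of the same size matched on expression. Most percentiles among those random lists are not given below. Members at least 25% higher in one library were counted. Stage lists share members with others, for example elavl3 and crestin.

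Shares of cells with a UMI were compared after thinning each cell to 4300 UMIs, which left out 828, 656, 826 and 1288 shallower cells. Class-standardised values average CPM over classes, weighting each class in every library by its share of the control library's UMIs, not of its cells. The other settings fixed then were minimums of 200 and 1000 genes, doublets kept, resolutions 0.5 and 2, ComBat by library, clusters from control alone with 15 nearest control cells, each cell's own highest marker score, median-of-ratios size factors, totals without mitochondrial, ribosomal and globin genes, equal weight per cell, class-standardised values, other expression minimums and unthinned shares.

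The ratio, interval and list steps were tested on simulated data, with 200 changed genes per comparison. Intervals held the true ratio for 95.2%, 95.0% and 95.2% of genes, and 20 of the 20 named genes were truly changed in each. Of 100 unchanged lists 8, 3 and 6 fell outside the central 95% of random lists. That simulation drew its counts from the same count model that the intervals assume, so their coverage was built in. It carries no variation between libraries, which the 4 libraries cannot show, and no variation between cells, which the ratio intervals also ignore. Free RNA was not subtracted, because empty droplets were not used here. Velocity, splicing and sequence variants were not analysed here.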

Results

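Whole wild-type zebrafish embryos were profiled at 12 hours post fertilization by droplet single-cell RNA sequencing, in which each captured transcript is counted by its unique molecular identifier (UMI). The 4 groups were an untreated control, embryos exposed to BMDBM (butyl methoxydibenzoylmethane, the ultraviolet-A sunscreen filter avobenzone), embryos exposed to particles that the labels call MPs, and embryos exposed to both (BMDBM+MPs). The labels give no dose, no particle size and no wording behind MPs, so reading MPs as particles is an assumption. In each group 40 embryos were pooled into 1 library, so no comparison has a replicate and none could be tested. Every interval is a 95% interval that covers counting error only, and all comparisons against control share the same control library.

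The files held 9877 cell barcodes and 179633824 UMIs in the control library, 10587 barcodes and 159078321 UMIs with BMDBM, 12878 and 178561060 with MPs, and 15687 and 186249222 with BMDBM+MPs. After filtering, 8363, 9412, 10992 and 13119 cells were kept in the same order. Their median depth was 12709 UMIs in control, 12690.5 with BMDBM, 10026 with MPs and 8614 with both. Clustering all kept cells together gave 39 clusters, which were given cell-class names from fixed marker genes. Cells without a class name made up 29.0% of the control library, 20.7% with BMDBM, 18.4% with MPs and 21.4% with both. The unnamed part included a mixed cluster with epidermal genes such as tp63 and cldni highest, forebrain markers next and 1.82 times the median UMI count, which held 8.71% of control cells, 3.23% with BMDBM, 3.07% with MPs and 4.72% with both.

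The series title asks about neurotoxicity, so the neural classes come first. Forebrain-like, midbrain-like, hindbrain-like, spinal cord-like, floor plate-like and differentiating neuron-like cells together made up 12.7% of the control library (exact binomial interval 12.0 to 13.5%). That share was 29.1% with BMDBM (28.1 to 29.99%), 26.0% with MPs (25.2 to 26.8%) and 23.5% with both (22.8 to 24.2%). The pooled neural share was higher in each exposed library than in control under all 13 other clusterings or cell choices, by at least 10.8 percentage points with BMDBM, 7.45 with MPs and 6.77 with both. Neural transcripts differed less than neural cell shares: the 34 measured neural progenitor and regional identity genes had a median log2 ratio to control of 0.21 with BMDBM, 0.09 with MPs and 0.18 with both over whole embryos. With every deposited barcode summed and no filter, those medians were 0.08, 0.03 and 0.13, and with the control's class make-up given to every library they turned to -0.20, -0.11 and -0.02.

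**Figure D1:**
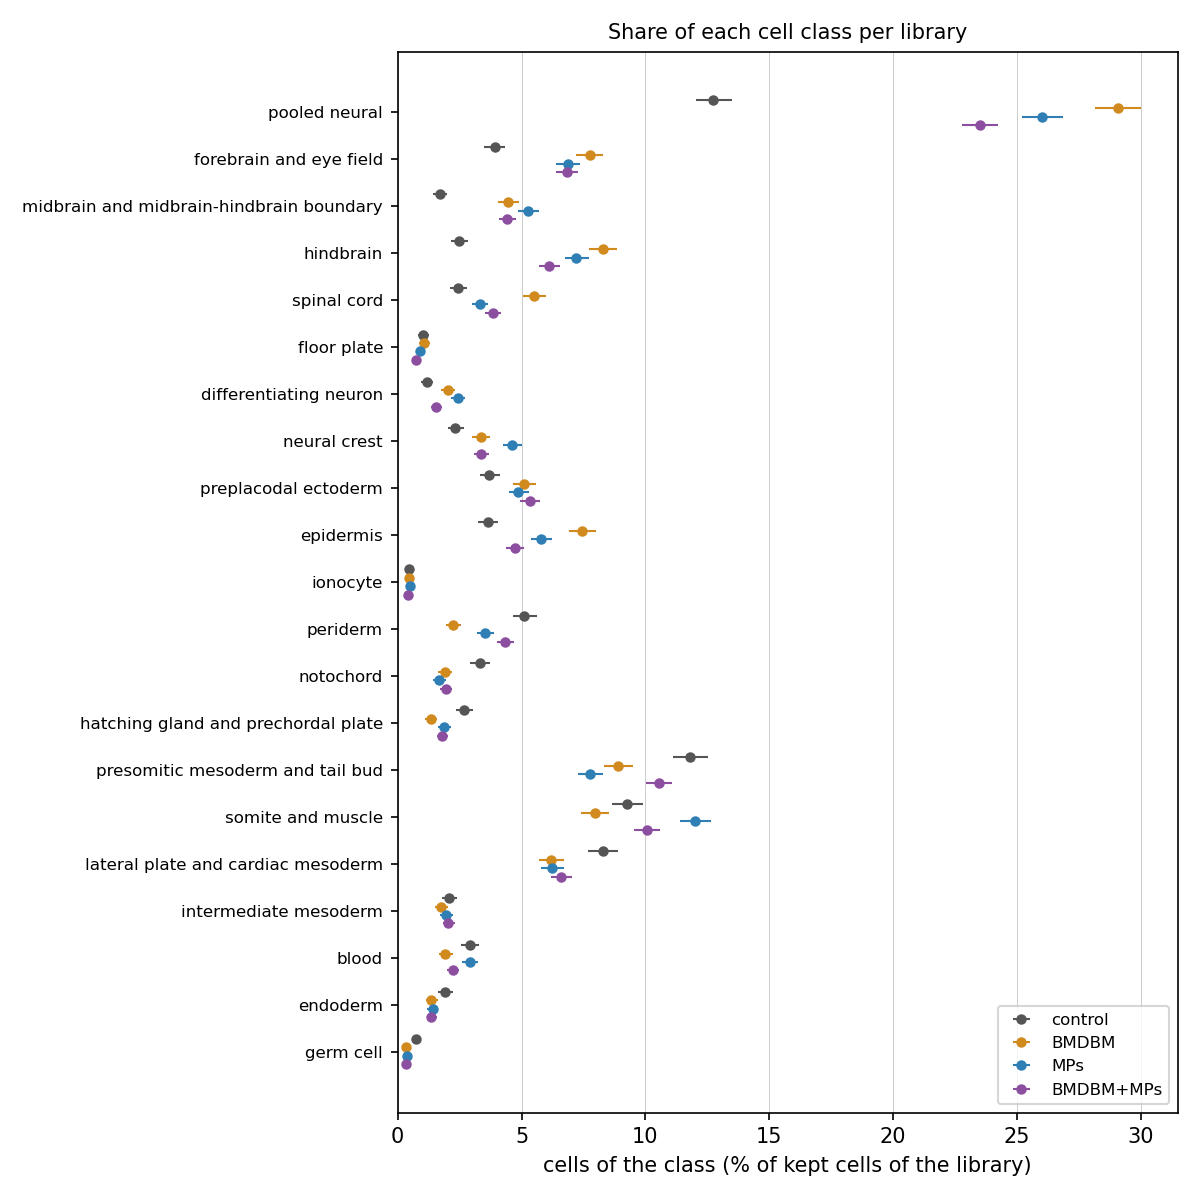
Share of each cell class among the kept cells of each library, in percent, with exact binomial 95% intervals for counting error. The pooled neural classes sit at 12.7% in control and between 23.5% and 29.1% in the 3 exposed libraries.

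The BMDBM library was set beside control to ask how the sunscreen filter alone was associated with the embryo's cells and genes. Inducible chaperone genes stood furthest above control, led by hsp70l (ENSDARG00000055723), an inducible Hsp70 chaperone, at 2000.2 CPM (UMIs scaled by the library's total) against 133, a ratio of 15.1 (14.8 to 15.3). hsp90aa1.2 (ENSDARG00000024746), an inducible Hsp90, stood at 1949.6 against 187 CPM, a ratio of 10.4 (10.3 to 10.5). The copies hsp70.1, hsp70.2 and hsp70.3 were 9.82-fold, 6.49-fold and 4.75-fold higher, and the co-chaperone genes DNAJA4, dnajb1b and hspbp1 were 7.19-fold, 3.75-fold and 2.49-fold higher. atf3, a stress-induced transcription factor, was 4.12-fold higher (3.83 to 4.43) and tent5ba was 3.11-fold higher. Zebrafish hsp70 copies are near-identical in sequence, so reads may be split between them and single copies are less certain than their sum. The sum of hsp70l, the 3 numbered hsp70 copies, hsp90aa1.2 and dnajb1b was 7.99-fold higher (7.94 to 8.03), at 0.709% of all UMIs against 0.0888% in control.

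The genes lowest with BMDBM were mostly genes of germ cells, periderm or hatching gland. afp4 was 24.9-fold lower (21.5 to 28.9; 1.45 against 36.2 CPM), and germ cells held 78.6% of its UMIs. The germ cell genes nanos3, ddx4 and ca15b, which encode germ plasm and germ cell factors, were 2.65-fold, 2.29-fold and 2.37-fold lower. Germ cells made up 0.329% of the BMDBM library against 0.741% of control. With the control's class make-up given to both libraries the nanos3, ddx4 and ca15b ratios were 0.931, 0.997 and 1.04, while that of afp4 stayed at 0.0434. icn2, elovl7a and gbgt1l4, with over 95% of their UMIs in periderm, the outer skin layer, were 1.97-fold, 1.95-fold and 1.90-fold lower, and with that make-up their ratios were 0.843, 0.841 and 0.869. hist1h2a4, a multi-copy histone gene, was 2.62-fold lower, phlda3, a DNA damage response gene, 1.99-fold lower, and the hatching enzyme gene he1.2 1.92-fold lower, with a ratio of 0.792 once the class make-up was shared. Over whole embryos, 16 of 4853 genes with at least 20 CPM in the higher library were 2-fold or more higher and 7 were 2-fold or more lower. This total of 23 rose to 77 with equal weight per cell and to 50 without the mixed cluster, and fell to 10 at a minimum of 100 CPM.

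Within BMDBM's neural classes, hindbrain-like cells differed most: 8.28% against 2.49% of control, a difference of 5.79 percentage points (5.14 to 6.44). Forebrain-like cells were 3.84 points more frequent, spinal cord-like cells 3.05 points, midbrain-like cells 2.74 points and differentiating neuron-like cells 0.847 points (0.481 to 1.21). The forebrain difference turned to -1.64 points when the mixed cluster was counted as neural, which places it in forebrain. Floor plate-like cells differed by 0.0448 points, with a counting interval from -0.255 to 0.345. Over the 13 clusterings or cell choices compared this difference ran from -0.0175 to 0.627 points and was positive in 12. No cluster was named hindbrain in 2 of the 13 clusterings or cell choices compared and none was named spinal cord in 6 of them, so the regional split is less firm than the neural total. Outside the nervous system, epidermis-like cells were 3.80 points more frequent, although the sign reversed at a coarser clustering. The mixed cluster, with epidermal genes highest, is not counted among them. It was 5.48 points less frequent with BMDBM, so the sign also depends on where that cluster is placed. Periderm-like cells were 2.87 points less frequent, notochord-like cells 1.42 points, hatching gland-like cells 1.35 points and presomitic mesoderm-like cells 2.92 points. Much of the presomitic difference lies in a cluster marked by mdm2, phlda3 and sesn3, with 2.36% of control and 0.691% of BMDBM cells. Part of the hatching gland difference lies in a cluster of low UMI counts, with 0.610% and 0.0637%. Lateral plate and cardiac mesoderm-like cells were 2.08 points less frequent (1.31 to 2.85). Shares are parts of a whole, so a higher neural share by itself lowers the shares of the other classes. How much of these lower shares arises that way was not tested. Unnamed cells were also less frequent with BMDBM, and the control's lower neural share stands beside its higher unnamed share.

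Fixed gene lists placed the BMDBM library as follows, with members counted as higher or lower when one library was at least 25% above the other. Over 15972 genes the median log2 ratio to control was -0.05 with BMDBM, -0.06 with MPs and -0.04 with both. List medians near those values do not stand apart from that general shift. Of 31 heat shock and unfolded protein response genes 12 were higher and 1 lower (median log2 ratio 0.19). Of 24 immediate early genes 12 were higher and 1 lower (median 0.48), with egr3 at 2.88-fold and klf2a at 0.68 of control. Of 34 neurogenesis genes 9 were higher and 5 lower (median 0.14), with olig2 at 1.70-fold, stmn1b at 1.48-fold and her4.1 at 0.72 of control. That median fell to 0.0152 with the control's class make-up and to 0.0511 over every deposited barcode. Of 34 neural progenitor genes 10 were higher and 2 lower, but their median turned from 0.21 to -0.20 when both libraries were given the control's class make-up. The glycolysis list had 11 of 22 members higher (median 0.32), among them eno1a, which encodes enolase, at 2.08-fold. Of 28 DNA damage response and apoptosis genes 13 were lower and 1 higher (median -0.23), with casp8 at 0.51 of control and mcl1a, an anti-apoptotic gene, at 1.80-fold. The cardiac and vascular list had 18 of 25 members lower (median -0.50), as had 12 of 25 lipid and yolk genes (median -0.29), where apoa1a stood at 0.36 against 6.66 CPM and fabp1b.1 at 0.21 against 4.86 CPM. With the control's class make-up both medians were -0.12. Lateral plate and cardiac mesoderm-like cells made up 6.19% with BMDBM against 8.27% of control, and blood-like cells 1.92% against 2.91%.

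In the aryl hydrocarbon receptor list 2 of 15 members were higher and 7 lower with BMDBM (median -0.26, and -0.06 with the control's class make-up). cyp1a, the classic target of that receptor, was at 1.39 CPM with BMDBM against 2.57 in control, 1.37 with MPs and 1.62 with both. ahr2, which encodes the receptor, was at 1.04, 1.39, 1.76 and 1.33 CPM in BMDBM, control, MPs and both. The estrogen receptor gene esr1 had no more than 3 UMIs in any library, so no ratio is given. The steroid and thyroid list had 4 of 12 members lower and 0 higher with BMDBM (median -0.23), and brain aromatase (cyp19a1b) was not analysed here. Antioxidant and metal response genes had 5 of 30 members lower and 0 higher (median -0.10).

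**Figure D2:**
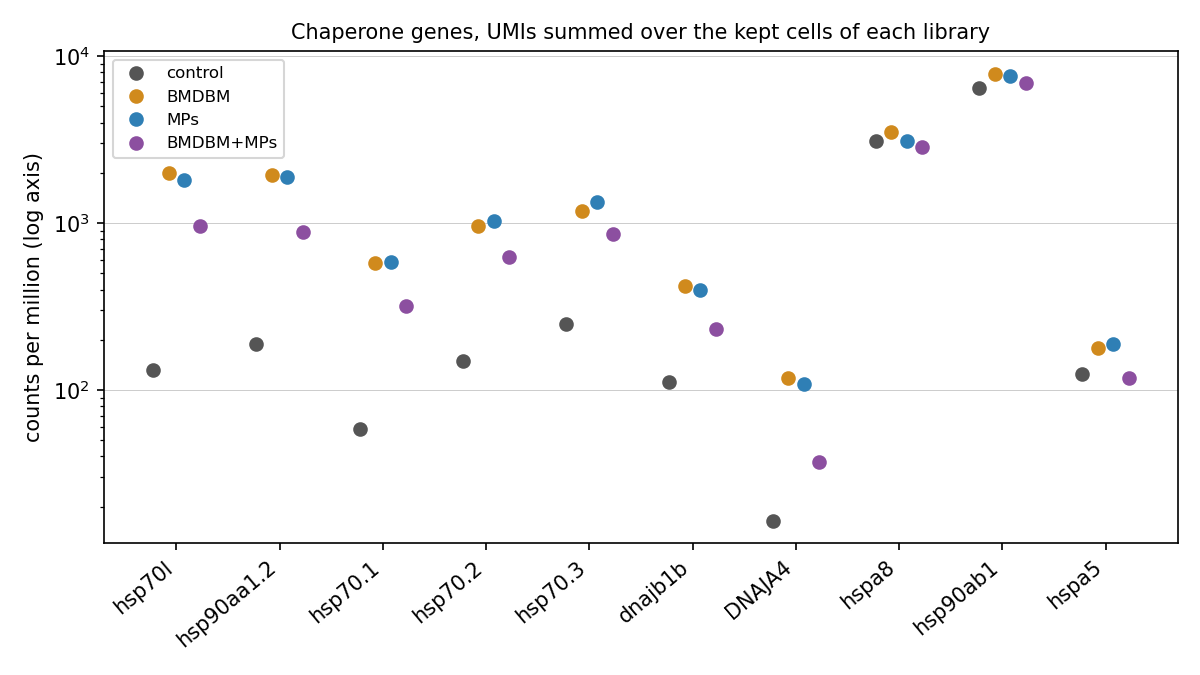
Chaperone genes in each library, in CPM of UMIs summed over kept cells, on a log axis. hsp70l stands at 133 CPM in control, 2000.2 with BMDBM, 1805 with MPs and 961 with both, while hspa8, hsp90ab1 and hspa5 lie within 2-fold of control in every library.

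The MPs library was set beside control to ask the same of the particles alone. The largest ratio belonged to hbbe3, an embryonic beta globin, at 47.6 against 1.05 CPM, or 45.2-fold higher (38.1 to 54.1). Globin genes are multi-copy, so this value is less certain for the single gene. ednrab, an endothelin receptor of the neural crest, was 15.5-fold higher (13.4 to 18.04), and tuba8l3, an alpha tubulin with 70.22% of its UMIs in differentiating neurons, was 5.34-fold higher (4.86 to 5.88). The chaperone genes stood high much as with BMDBM: hsp70l 13.6-fold (13.4 to 13.8), hsp90aa1.2 10.1-fold, hsp70.1 9.88-fold, hsp70.2 6.90-fold, DNAJA4 6.62-fold and hsp70.3 5.42-fold higher, and the 6-gene sum 7.92-fold higher (7.88 to 7.97). atf3 was 4.75-fold higher.

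At the low end with MPs stood gsc, an organizer and prechordal plate gene, 6.24-fold lower (5.69 to 6.85), and hist1h2a4, 4.08-fold lower. The leukocyte and periderm gene lcp1 was 3.91-fold lower, alox5b.3 3.43-fold and cyba 2.46-fold, with 97.2%, 91.6% and 70.4% of their UMIs in periderm. The stress response genes phlda3 and sesn3 were 3.60-fold (3.40 to 3.82) and 2.82-fold lower. szl, a ventral gene of the gastrula, was 2.65-fold lower, cdx1a, a posterior homeobox gene, 2.44-fold and the germ cell gene ca15b 2.61-fold. With the control's class make-up the ca15b ratio was 0.732, germ cells making up 0.391% with MPs against 0.741% of control. MPs stood further from control than the other exposed libraries by the count of genes: 52 of 4919 were 2-fold or more higher and 32 lower. This total of 84 was 94 with equal weight per cell, 98 without the mixed cluster and 18 at a minimum of 100 CPM.

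Later-stage genes had the median furthest from 0 among the lists with MPs. Of 32 genes of later stages 27 were higher and 1 lower (median log2 ratio 1.07), with mylpfa, a fast muscle myosin light chain, 9.16-fold higher (6.77 to 12.7). Of 28 gastrula genes 23 were lower and 0 higher (median -0.69), among them ndr2, a Nodal ligand, at 0.13 of control. With the control's class make-up the medians were 0.90 and -0.45. Embryos at a later stage would give the same direction, and stage and exposure cannot be told apart with 1 library per group. That limit also holds for the globin, muscle, neuronal, crest and gastrula genes named with MPs. Neurogenesis genes were higher in 16 of 34 members and lower in 2 (median 0.29), led by the neuronal genes stmn2b at 5.66-fold (3.80 to 8.72) and elavl4 at 4.54-fold (3.68 to 5.64), while the Notch ligand dld stood at 0.64 of control. The neurogenesis median was 0.16 with the control's class make-up. Axon guidance and adhesion genes were higher in 11 of 27 members and lower in 3 (median 0.28), with epha4b at 2.80-fold. In the neural crest list 7 of 19 members were higher and 2 lower (median 0.23), with crestin at 4.40-fold and foxd3, an early crest factor, at 0.43 of control, and the crest median was 0.02 with the control's class make-up.

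Other lists in the MPs library went both ways. Immediate early genes were higher in 19 of 24 members (median 0.90), including egr3 at 6.27-fold (4.60 to 8.71). The DNA damage response and apoptosis list had 13 of 28 members lower and 5 higher (median -0.31), with the pro-apoptotic gene bbc3 at 0.26 of control. Heat shock and unfolded protein genes were higher in 13 of 31 members and lower in 1, the small heat shock gene hspb1 at 0.54 of control (3729 against 6851 CPM). In the cardiac and vascular list 12 of 25 members were higher and 11 lower (median 0.16), with the cardiac troponin gene tnnt2a 6.59-fold higher and gata5 at 0.48 of control. Lipid and yolk genes had 8 of 25 members higher and 12 lower, and their median turned from -0.12 to 0.01 with the control's class make-up. sod2, the mitochondrial superoxide dismutase, stood at 0.37 of control, although 6 of 30 antioxidant genes were higher and 3 lower. Ribosomal protein genes were at least 25% higher in 8 of 47 members (median 0.19).

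Among the neural classes with MPs, hindbrain-like cells differed most in percentage points, at 7.21% against 2.49% of control, 4.73 points more (4.14 to 5.31). Midbrain-like cells followed at 5.27% against 1.71%, 3.56 points more (3.06 to 4.06). By ratio midbrain-like cells came first, at 3.08-fold against 2.90-fold for hindbrain-like cells. Forebrain-like cells were 2.96 points more frequent, but 2.67 points less frequent with the mixed cluster counted among them. Differentiating neuron-like cells were 1.26 points more frequent (0.888 to 1.63), spinal cord-like cells 0.872 points and neural crest-like cells 2.29 points. Floor plate-like cells differed by -0.109 points with an interval from -0.390 to 0.171. Somite-like cells made up 12.0% against 9.27% in control, 2.74 points more (1.87 to 3.61). Presomitic mesoderm-like cells were 4.05 points less frequent (3.20 to 4.91), notochord-like cells 1.64 points, periderm-like cells 1.58 points and hatching gland-like cells 0.807 points. Much of the presomitic difference lies in the cluster marked by mdm2, phlda3 and sesn3, with 2.36% of control and 0.136% of MPs cells. Lateral plate and cardiac mesoderm-like cells were 2.04 points less frequent (1.299 to 2.79). Here too the higher neural share by itself lowers the shares of the other classes.

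The co-exposed library was set beside control to ask how both together were associated with the same measures. Chaperone genes again stood highest, at lower ratios: hsp70l 7.24-fold (7.12 to 7.36), hsp70.1 5.43-fold, hsp90aa1.2 4.74-fold, hsp70.2 4.203-fold, hsp70.3 3.48-fold, DNAJA4 2.23-fold and dnajb1b 2.05-fold. Next came fosab, an immediate early gene, at 1.93-fold, the transcription factor gene sp8a at 1.87-fold and fabp3, a fatty acid binding protein gene, at 1.83-fold. The lowest were afp4 at 22.1-fold lower (19.3 to 25.5), hist1h2a4 at 3.63-fold, gsc at 2.54-fold and nanos3 at 1.98-fold lower. With the control's class make-up the nanos3 ratio was 0.917, germ cells making up 0.328% with both against 0.741% of control. kdelr3, ddit4, spsb4a, the cardiac factor genes gata5 and nkx2.7, and tmem88a lay between 1.83-fold and 1.94-fold lower. Of 4851 genes, 7 were 2-fold or more higher and 6 lower, a total of 13 that became 23 with equal weight per cell.

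In the co-exposed library 11 of 24 immediate early genes were higher and 1 lower (median log2 ratio 0.29). Neurogenesis genes were higher in 10 of 34 members and lower in 0 (median 0.09, and 0.043 over every deposited barcode), with ascl1a, a proneural factor, at 1.80-fold (1.62 to 1.99), and axon guidance genes in 5 of 27 (median 0.11). The DNA damage response and apoptosis list had 11 of 28 members lower and 1 higher (median -0.21), with gadd45aa at 0.38 of control. Gastrula genes had 15 of 28 members lower and 0 higher (median -0.36). Later-stage genes had 13 of 32 higher and 3 lower (median 0.15). Cardiac and vascular genes had 9 of 25 lower and 5 higher, with a median that turned from -0.18 to 0.02 with the control's class make-up. Hindbrain-like cells were 3.64 points more frequent than in control (3.11 to 4.17), forebrain-like cells 2.93 points, midbrain-like cells 2.71 points and spinal cord-like cells 1.40 points, while floor plate-like cells were 0.304 points less frequent, with a sign that reversed in 2 of the alternatives. The forebrain difference turned to -1.06 points with the mixed cluster counted as neural.

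**Figure D3:**
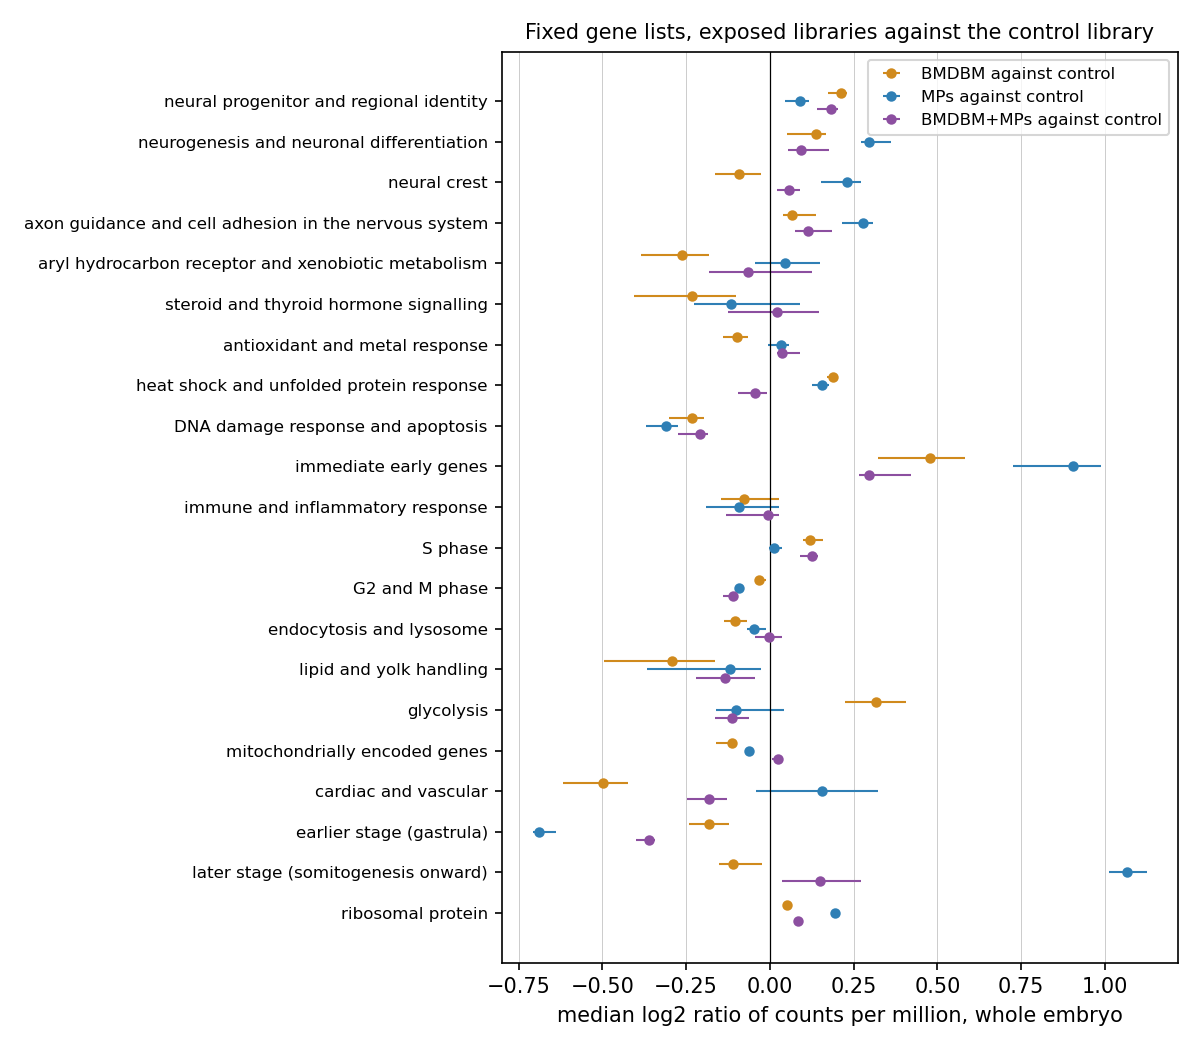
Median log2 ratio to control of each fixed gene list over whole embryos, with bars for counting error. Later-stage genes reach 1.07 with MPs, and DNA damage response and apoptosis genes lie between -0.31 and -0.21 in the 3 exposed libraries.

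The co-exposed library was then set beside each single exposure to ask what the second agent was associated with. Against BMDBM, the 6-gene chaperone sum stood at 0.548 (0.547 to 0.550), and against MPs at 0.553 (0.551 to 0.555). Single genes against BMDBM were DNAJA4 3.22-fold lower, hspbp1 2.95-fold, atf3 2.64-fold, dnajb1a 2.25-fold, hsp90aa1.2 2.19-fold and hsp70l 2.08-fold lower. spsb4a and pdcd4b were 2.07-fold and 2.03-fold lower, p4ha1b, a collagen prolyl hydroxylase gene, 1.91-fold and arrdc3b 1.87-fold. At the high end against BMDBM stood 9 genes with most of their UMIs in periderm, between s100a10b at 2.02-fold (1.94 to 2.10) and tm9sf5 at 1.79-fold, and he1.2 at 1.87-fold. Periderm-like cells were 2.08 points more frequent than with BMDBM, and with a shared class make-up these 9 ratios lay between 1.14 and 1.37. Glycolysis genes had 12 of 22 members lower than with BMDBM (median -0.35), with eno1a at 0.302.

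Against MPs, the lowest genes of the co-exposed library were the following: hbbe3 was 5.31-fold lower (4.99 to 5.66), ednrab 4.86-fold, tuba8l3 3.18-fold, myl13, a muscle myosin light chain, 3.14-fold, the myeloid factor gene spi1b 2.77-fold, hbbe1.1 2.59-fold and the skeletal actin gene acta1b 2.47-fold lower. Stress genes atf3, DNAJA4 and hspbp1 were 3.04-fold, 2.96-fold and 2.72-fold lower. Higher than with MPs were alox5b.3 at 4.02-fold (3.72 to 4.35), lcp1 at 2.94-fold, the forebrain gene six7 at 2.24-fold, sesn3 at 2.16-fold and phlda3 at 2.003-fold. s100a1, rcc1l, arr3b, rx3, an eye field factor, and her5, a midbrain factor, lay between 1.66-fold and 1.97-fold higher. Later-stage genes had 29 of 32 members lower (median -0.95) and neurogenesis genes 14 of 34 lower and 1 higher (median -0.26, and -0.08 with a shared class make-up). In the neural crest list 6 of 19 members were lower and 1 higher (median -0.14).

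Pooled neural cells were 5.56 percentage points less frequent with both agents than with BMDBM (4.39 to 6.73) and 2.51 points less frequent than with MPs (1.41 to 3.61). The second of these differences narrowed to 0.372 points when each cell took the class of its own highest marker score. The counts of genes 2-fold or more apart were 4 higher and 11 lower against BMDBM, and 6 higher and 24 lower against MPs.

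A product of the 2 single-exposure ratios was used as a reference for the co-exposed ratio, and the log2 departure from it was described. An offset shared by all exposed libraries, or a control library that stood apart, would by itself give a departure of opposite sign. The departure cannot separate such an offset from an action of one agent on the other. Among 4027 genes with at least 20 CPM in every library the median departure was 0.11. The 5 lowest genes were hsp70l at -4.82 (-4.85 to -4.80), hsp90aa1.2 at -4.46, hsp70.1 at -4.16, hsp70.2 at -3.41 and hsp70.3 at -2.88. The 5 highest were spaca4l at 1.52, nanos3 at 1.41, s100a1 at 1.24, mboat1 at 1.19 and nqo1, a quinone reductase gene, at 1.18. With a shared class make-up nanos3 stood at 0.03, mboat1 at 0.37, nqo1 at 0.40 and spaca4l at 0.73, while s100a1 stood at 1.201. The pooled neural share departed by -1.34 (-1.46 to -1.21): the product of the single-exposure ratios would give 59.3% of cells, against 23.5% observed. Shares are parts of a whole, and products taken class by class need not add up to a whole. Part of a negative departure of a raised share may therefore be built in. With unresolved neural clusters counted the departure was -1.08. With the mixed cluster counted as neural the shares were 21.5% in control, 32.3% with BMDBM, 29.1% with MPs and 28.2% with both, which gives a smaller departure.

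Chaperone transcripts were spread over cell classes. Among the 6 classes with at least 300 cells in every library, the 6-gene sum was between 5.53-fold (somite) and 10.3-fold (epidermis) higher than control with BMDBM, between 5.97-fold and 10.4-fold with MPs, and between 3.92-fold and 5.01-fold with both. In cells thinned to 4300 UMIs the median cell held 3 UMIs of the 6 genes in control, 29 with BMDBM, 29 with MPs and 16 with both. Germ cells had the smallest ratios, 2.498-fold with BMDBM (2.28 to 2.73), 2.52-fold with MPs and 1.83-fold with both, from as few as 31 cells in a library.

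**Figure D4:**
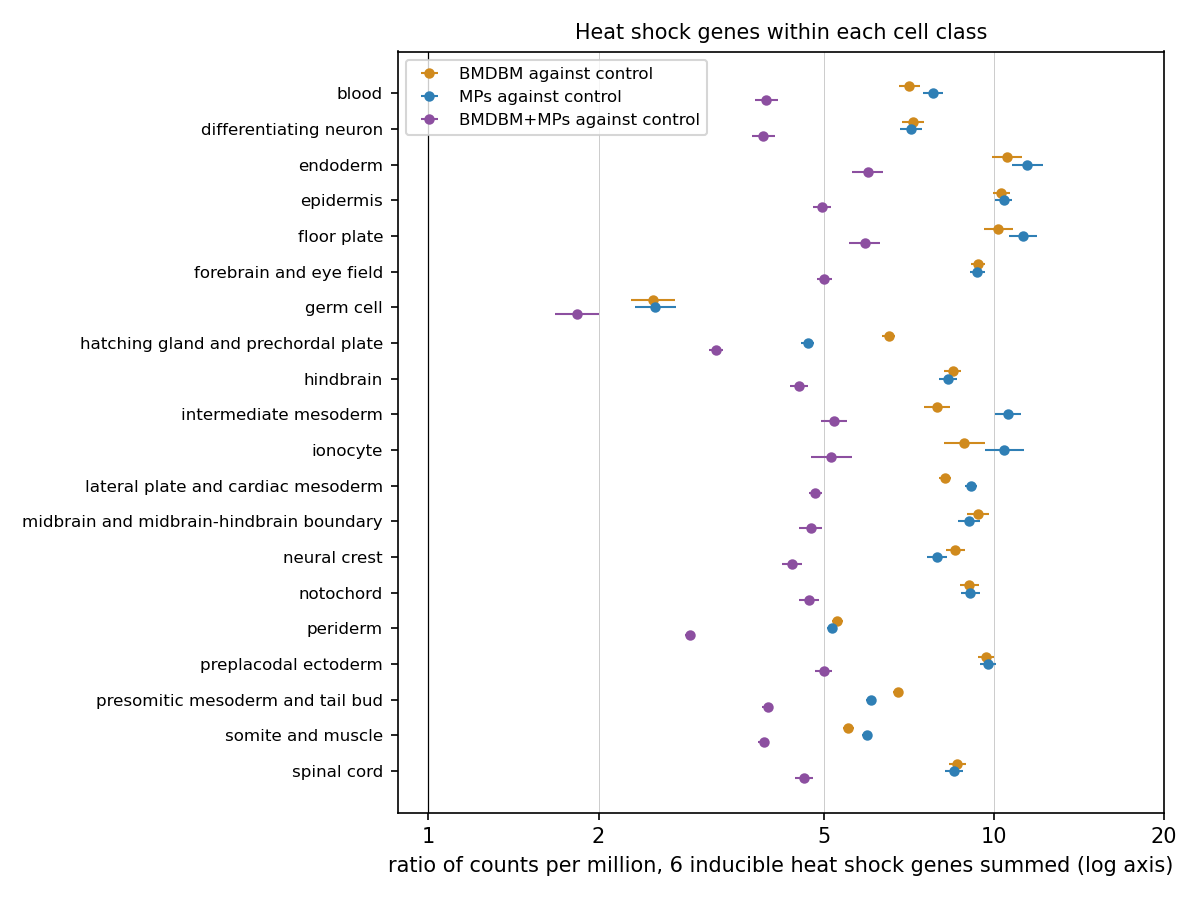
Ratio of the summed CPM of 6 inducible chaperone genes in each exposed library to control, per cell class, on a log axis, with bars for counting error. All classes lie above 1, from 1.83 in germ cells with both agents to 11.5 in endoderm with MPs.

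Inside the pooled neural cells the chaperone genes were again highest: hsp70l was 15.6-fold higher than control with BMDBM, 13.8-fold with MPs and 7.36-fold with both, and hsp70.1 was 12.2-fold, 12.0-fold and 6.43-fold higher. hsp90aa1.2 was 10.98-fold, 11.1-fold and 4.91-fold higher, and DNAJA4 was 9.17-fold and 8.48-fold higher in the single exposures. The lowest genes were mostly mesodermal: with BMDBM her7, msgn1, tbx16, myf5 and szl were 10.5-fold, 10.0-fold, 8.36-fold, 7.53-fold and 6.55-fold lower. With both agents szl, ttn.1, tbx16, meox1 and pcdh8 were 8.47-fold, 4.46-fold, 4.37-fold, 4.21-fold and 4.16-fold lower. With MPs szl, her7, rims2b, cdx1a and phlda3 were 10.4-fold, 6.86-fold, 5.61-fold, 5.40-fold and 5.12-fold lower. Control's neural cells carried more mesodermal RNA, with 12 somite markers at 3.30% of their level in somite-like cells, against 0.582% with BMDBM, 1.02% with MPs and 0.964% with both. These somite markers include myf5, ttn.1 and meox1, named above, so their level partly repeats those genes. For 12 presomitic markers, among them her7, msgn1 and tbx16, the level in control was 7.70% of that in presomitic-like cells. It was 3.89% with BMDBM, 3.66% with MPs and 4.39% with both, a smaller gap by ratio. Between libraries, 76, 121 and 55 genes were 2-fold or more apart from control in these cells with BMDBM, MPs and both.

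Neuronal genes inside the pooled neural cells did not follow the cell shares. elavl3, a marker of postmitotic neurons, stood at 328 CPM in control, 269 with BMDBM, 362 with MPs and 281 with both. neurog1, a proneural factor, stood at 218, 231, 198 and 173 CPM, and sox2, a progenitor factor, at 162, 156, 145 and 157 CPM. The neurogenesis list had 1 of 33 members higher and 17 lower with BMDBM (median log2 ratio -0.34), 10 higher and 6 lower with MPs (0.05), and 3 higher and 14 lower with both (-0.24). Differentiating neuron-like cells made up 9.19% of the pooled neural cells in control, 6.95% with BMDBM, 9.34% with MPs and 6.58% with both. After thinning to 4300 UMIs, elavl3 was seen in 29.1%, 29.1%, 28.3% and 26.5% of the pooled neural cells. Over whole embryos elavl3 stood at 72.4, 100.3, 122 and 91.5 CPM, neurog1 at 71.7, 98.4, 75.3 and 72.2 CPM, and sox2 at 65.4, 75.0, 68.4 and 73.9 CPM, in control, BMDBM, MPs and both. With the control's class make-up the sox2 ratio was below 1 in each exposed library, at 0.876, 0.917 and 0.985. In thinned cells of the whole embryo, elavl3 was seen in 8.41% of control cells, 12.2% with BMDBM, 11.2% with MPs and 9.81% with both, against 17.0%, 21.1%, 18.8% and 16.4% unthinned. In somite-like cells, which should lack it, the thinned shares were 1.54%, 0.590%, 1.38% and 1.61%, at unthinned median depths of 11911, 11950.5, 9486.5 and 7763.5 UMIs.

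Other classes with at least 300 cells in each library repeated the chaperone result, and differed in a few more genes. In somite-like cells with MPs the myosin light chain genes myl4 and mylpfa were 11.3-fold (8.06 to 16.2) and 10.4-fold (7.28 to 15.5) higher. In preplacodal-like cells with MPs cxcl14, a chemokine gene, was 29.6-fold higher (19.1 to 48.8), and in epidermis-like cells dkk1a, a Wnt antagonist gene, stood at 20.6 against 0.225 CPM. szl was 9.71-fold lower in epidermis-like cells with MPs. In presomitic-like cells phlda3 was 16.3-fold lower with MPs (11.3 to 24.3) and 4.13-fold lower with BMDBM, and isg15 was 10.4-fold lower with MPs. A cluster marked by mdm2, phlda3 and sesn3 held 197 of the control's presomitic-like cells, 65 with BMDBM, 15 with MPs and 153 with both. In somite-like cells with BMDBM hand2 and tal1, genes of lateral plate and blood, were 33.999-fold and 11.5-fold lower. In the same class 10 lateral plate markers stood at 5.06% of their own-class level in control against 0.688% with BMDBM. hand2 is among these 10 and held 477 of their 783 UMIs in control, so that level largely repeats the hand2 result. In epidermis-like cells with BMDBM the somite gene tcf15 was 22.2-fold lower and fsta 16.3-fold, and in preplacodal-like cells en2b and foxd3 were 18.5-fold and 9.05-fold lower. en2b and foxd3 are markers of midbrain and neural crest, and RNA from other classes was not separated from a difference within the class. The en2b ratio rests on 105 UMIs in control and 7 with BMDBM. en2b stood there at 21.7 CPM in control, 1.18 with BMDBM, 37.3 with MPs and 17.1 with both.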

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

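Among the tests below, the one of a warmer or longer dissociation, those counting removed barcodes, the mixed cluster or removed doublets as neural, the one of dissociation stress in the neural DNA damage response cluster alone and the one of damage in the presomitic cluster alone were chosen only after the result was seen. The first results given here stand out because a gene's ratio for an agent lay on opposite sides of 1 without and with the other agent. These contrasts were not tested, since each group has 1 library. An offset shared by all exposed libraries would move the ratio without the other agent but not the one with it. Part of each departure could therefore arise without an action of one agent on the other. For hsp70l, with a log2 departure from the product of single exposures of -4.82, the ratio for BMDBM was 15.1 without MPs and 0.532 with them, and that for MPs was 13.6 without BMDBM and 0.480 with it. hsp90aa1.2 departed by -4.46, with ratios of 10.4 and 0.471 for BMDBM and 10.1 and 0.456 for MPs. hsp70.1 departed by -4.16, with 9.82 and 0.550 for BMDBM and 9.88 and 0.553 for MPs. hsp70.2 departed by -3.41, with 6.49 and 0.609 for BMDBM and 6.90 and 0.647 for MPs, and hsp70.3 by -2.88, with 4.75 and 0.643 for BMDBM and 5.42 and 0.734 for MPs.

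Genes on the other side went from below to above 1, also not tested. spaca4l departed by 1.52, with ratios of 0.541 and 1.55 for BMDBM and 0.599 and 1.71 for MPs. nqo1 departed by 1.18, with 0.575 and 1.31 for BMDBM and 0.628 and 1.42 for MPs. For MPs alone, nanos3 (1.41) went from 0.503 to 1.34 and mboat1 (1.19) from 0.678 to 1.55. With a shared class make-up these departures shrank to 0.73 for spaca4l, 0.40 for nqo1, 0.03 for nanos3 and 0.37 for mboat1.

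The control library held fewer neural cells than the exposed libraries, and barcodes removed for few genes or a high mitochondrial share, together with the mixed cluster, are argued against as the place of all the missing neural cells: counting all of them as neural in control gave 24.4% (up to 25.4%), against at least 27.6% (from 26.8%) in the exposed libraries with the mixed cluster alone counted. Removed doublets alone are argued against in the same way, since counting each once as neural in control and none elsewhere gave 19.04% (up to 19.9%) against at least 20.7% (from 20.05%), and with doublets kept the exposed shares were still 13.5, 11.8 and 9.03 points higher. Barcodes with the most UMIs, and several of these places together, stay open as a cause that may lie in capture, because the test over every deposited barcode was void: its largest neural progenitor median was 0.13, but the kept cells' medians of 0.21, 0.09 and 0.18 already lay under the 0.3 needed to argue against it. A difference in stage stays open too, since the class-standardised stage medians lay no nearer to 0 than 0.11. BMDBM, the library with the highest neural share, was at -0.11 for gastrula genes and 0.14 for later genes. MPs stood furthest from 0 in the direction of a later stage, at -0.45 and 0.90, and both agents together stood at -0.24 and 0.27. An effect of the exposures was not tested, and the explanations left open cannot be told apart with 1 library per group.

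Clusters 24, with neural markers, and 31, with presomitic markers, were high in the DNA damage response genes mdm2, cdkn1a and phlda3 in all 4 libraries, control included. They were picked for such genes among their 10 top genes, so a high level over the libraries together follows from that choice. In cluster 24 mdm2 was 2.34-fold higher than in other neural cells with MPs. It was 4.79-fold, 7.25-fold and 7.21-fold higher in control, BMDBM and both. In the neural cluster immediate early genes were no higher than in other neural cells, with a highest median log2 fold of -0.38. This argues against stress during dissociation particular to that cluster, which was set apart after its values were seen. Stress shared by all cells would not show in this comparison. In cluster 31 dissociation stress may still contribute, with 0.13 under BMDBM. For cluster 31 alone, damaged or leaking cells are argued against, with mitochondrial shares of at most 1.1997 times (bound 1.27) and UMI counts of at least 0.931 times (bound 0.776) those of other presomitic cells. For the neural cluster damage stays open, since UMI counts were 0.598, 0.689, 0.634 and 0.812 times those of other neural cells in control, BMDBM, MPs and both, although the mitochondrial shares of 0.161, 0.260, 0.0951 and 1.09 times reached in no library the 1.5 times that damage predicted. No biological explanation was tested; both clusters held a smaller share of each exposed library than of control, where they held 3.09% and 2.36% of cells.

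Inducible heat shock genes were higher in all 3 exposed libraries. A subset of damaged cells is argued against, because the 10% of cells with the most of these UMIs held at most 19.3% of them. A warmer or longer dissociation of the exposed libraries may also raise them in every class: the ratio of a class lay between 0.63 and 1.17 times the median over 6 classes, and immediate early genes were higher in the same libraries (medians 0.48, 0.90 and 0.29 with BMDBM, MPs and both). That handling and the exposures cannot be told apart, because each group was dissociated as 1 library. An effect of the exposures was not tested.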

How the results depend on the processing

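The alternatives with the mixed cluster, the DNA damage response clusters, neural clusters of unresolved region, variable genes left out and every deposited barcode were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and for the same reason none could be left out. Except where the construction is named, the cause was not tested. Of 65 alternative values of the neural share 36 stayed within their interval, 29 moved and 0 reversed. The counts were 489, 112 and 17 of 618 for class shares, 814, 221 and 15 of 1050 for list medians, 915, 327 and 8 of 1250 for named genes, 46, 14 and 0 of 60 for counts of genes 2-fold apart, 2, 18 and 0 of 20 for departures, and 2, 30 and 0 of 32 for shares of cells with a UMI.

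The neural share of the BMDBM library was 16.3 points above control. That difference was 14.9 with a minimum of 200 genes, 14.4 with 1000 genes, 13.5 with doublets kept, 14.4 at resolution 0.5, 12.4 at resolution 2, 12.99 with ComBat, 13.05 by each cell's own score and 10.8 with the mixed cluster counted as neural. For MPs (13.3) it was 11.8 with doublets kept, 11.8 at resolution 2, 10.3 with ComBat, 12.0 without variable genes 2-fold apart between libraries, 7.45 by own score, 7.63 with the mixed cluster as neural and 12.1 with unresolved neural clusters counted. For both agents (10.8) it was 9.48 with 1000 genes, 9.03 with doublets kept, 9.13 at resolution 2, 8.10 with ComBat, 7.08 by own score and 6.77 with the mixed cluster as neural. Against BMDBM the co-exposed share (-5.56) moved to -4.11 at resolution 0.5, -3.27 at resolution 2, -4.07 with the mixed cluster and -6.88 with unresolved clusters. Against MPs (-2.51) it moved to -3.61 with 1000 genes, -1.40 without those variable genes, -0.372 by own score and -0.866 with the mixed cluster. The mixed cluster lowers the differences by construction, since it made up a larger share of control cells than of any exposed library.

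Some class differences reversed. By own score, preplacodal-like cells went from 1.40, 1.17 and 1.62 points to -0.724, -0.675 and -0.406 for BMDBM, MPs and both, neural crest-like cells with BMDBM from 1.03 to -0.399, floor plate-like cells with both from -0.304 to 0.311 and blood-like cells with both from -0.680 to 0.102. At resolution 0.5, epidermis-like cells went to -1.27, -3.04 and -2.84 and presomitic-like cells with both from -1.26 to 0.203. With control clusters, floor plate-like cells with both were at 0.0297, epidermis-like cells with MPs at -0.435 and presomitic-like cells with both at 0.106. With doublets kept the last were at 0.0561. With the mixed cluster counted as neural, which places it in forebrain, forebrain-like cells were at -1.64, -2.67 and -1.06.

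Class-standardised values, which remove class make-up by construction, turned the neural progenitor median to -0.196, -0.108 and -0.0165 for BMDBM, MPs and both. They also gave -0.0454 for S phase with BMDBM and 0.0753 against BMDBM, 0.013 for lipid genes with MPs, 0.0164 for cardiac and vascular genes with both, 0.14 for later-stage genes with BMDBM, and 0.0334 for heat shock genes with both. Genes that reversed this way were ca15b with BMDBM (0.0588), sox2 (-0.19, -0.13 and -0.0218), neurog1 with MPs (-0.19) and against MPs (0.0143), and elavl3 against BMDBM (0.0707). With every deposited barcode neurog1 with MPs was at -0.12, heat shock genes with both at 0.0424, later-stage genes with BMDBM at 0.0838 and S phase against BMDBM at 0.0108. Size factors gave 0.0202 for G2 and M phase with BMDBM and 0.0128 for endocytosis with MPs; totals without mitochondrial, ribosomal and globin genes gave 0.0137 for the last.

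The neurogenesis median with BMDBM (0.14) was 0.19 with size factors, 0.18 with equal weight per cell, 0.0152 class-standardised and 0.0511 over every barcode. With MPs (0.29) it was 0.47 with equal weight, 0.16 class-standardised, 0.27 over every barcode and 0.37 without the mixed cluster. With both (0.09) it was 0.20 with equal weight, 0.0476 with doublets kept and 0.043 over every barcode.

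Counts of genes 2-fold apart followed the expression minimum, since a lower one admits more genes. At 3 UMIs they were 1734, 2785 and 1724 for BMDBM, MPs and both, 1819 against BMDBM and 2042 against MPs; at 100 CPM they were 10, 18, 6, 3 and 5. Equal weight per cell gave 77 for BMDBM and 23 for both, leaving out the mixed cluster gave 50 for BMDBM, and totals without mitochondrial, ribosomal and globin genes gave 47 against MPs. Depth limits rare genes: esr1 had at most 3 UMIs in a library.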

Other observations

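Smaller differences also ran through metabolism and immediate early genes of the pooled neural cells. Lipid and yolk genes in the pooled neural cells had a median log2 ratio of 0.65 with MPs and 0.25 with both, against -0.11 with BMDBM. fabp7a, a radial glia fatty acid binding protein gene, was 3.28-fold higher there with MPs, while apoc1 stood at 0.24 of control. Glycolysis genes were at least 25% higher in 9 of 18 measured members in these cells with BMDBM (median 0.33), while their medians were -0.15 with MPs and -0.16 with both. Immediate early genes had medians of 0.30, 0.68 and 0.24 in the pooled neural cells with BMDBM, MPs and both, and junba was 3.83-fold, 4.94-fold and 2.82-fold higher.

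The cardiac and vascular list in the co-exposed library had 14 of 25 members higher and 4 lower against BMDBM (median 0.42), and 2 higher and 11 lower against MPs (-0.19). With a shared class make-up these medians were 0.24 and -0.07. Against BMDBM, 12 of 25 lipid and yolk genes were higher and 1 lower with both agents (median 0.29), and against MPs 3 were higher and 14 lower (-0.36). An unnamed cluster with spi1b, etv2 and tal1 held 0.992% of control cells, 0.627% with BMDBM, 1.246% with MPs and 1.07% with both.

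The lists not described so far are given over whole embryos as medians for BMDBM, MPs and both against control, and a median near 0 can hide members on either side. S phase genes were at 0.12, 0.01 and 0.12, with the first turning to -0.05 when class-standardised, and G2 and M phase genes were at -0.03, -0.09 and -0.11, the first turning to 0.02 with size factors. Immune and inflammatory genes were at -0.08, -0.09 and -0.01. Endocytosis and lysosome genes were at -0.10, -0.05 and -0.00, the second turning to 0.01 with size factors. Mitochondrially encoded genes were at -0.11, -0.06 and 0.02, and ribosomal protein genes at 0.05, 0.19 and 0.08. The heat shock and unfolded protein list was at -0.04 with both and at 0.15 with MPs, the former turning to 0.03 when class-standardised. Neural crest genes were at -0.09 with BMDBM and 0.06 with both, axon guidance genes at 0.07 with BMDBM, and antioxidant genes at 0.03 with MPs and 0.04 with both. Among random lists matched on expression, the neural crest medians stood at percentile 15.4 with BMDBM and 94.8 with both. Those random lists centred on -0.04 in each case. Aryl hydrocarbon receptor genes were at 0.04 with MPs and -0.07 with both, and steroid and thyroid genes at -0.12 with MPs and 0.02 with both. Glycolysis genes were at -0.10 with MPs and -0.11 with both, lipid and yolk genes at -0.13 with both, and gastrula and later-stage genes at -0.18 and -0.11 with BMDBM, the last turning to 0.14 when class-standardised. Members went both ways in several of these lists: with BMDBM 9 of 32 later-stage genes were higher and 11 lower, and 3 of 28 gastrula genes higher and 10 lower. With both agents 4 of 25 lipid and yolk genes were higher and 9 lower, and 7 of 31 heat shock and unfolded protein genes higher and 2 lower. Endocytosis and lysosome genes with MPs had 6 of 35 members higher and 5 lower, and immune genes 4 of 22 higher and 6 lower.

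In the pooled neural cells against BMDBM, the periderm keratin genes krt5, krt4 and krt17 were 2.82-fold, 2.43-fold and 2.34-fold higher with both agents, msgn1 2.78-fold and tmsb1 3.003-fold higher. p4ha1b, pdcd4b, DNAJA4, hspbp1 and p4ha2 were 6.13-fold, 4.05-fold, 3.58-fold, 2.92-fold and 2.78-fold lower. Periderm markers in those neural cells stood at 0.108% of their own-class level with BMDBM and 0.307% with both. The keratin genes krt5, krt4 and krt17 are among these markers, so that level partly repeats them. Against MPs, six7, shisa2a, cxcr4a, apoc1 and rcc1l were between 2.08-fold and 2.42-fold higher, and pdcd4b, DNAJA4, tuba8l3, hapln1a and hspbp1 between 2.64-fold and 3.53-fold lower.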
